A study of Cereibacter sphaeroides with 2 samples.

How the data were processed

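Total RNA of *Cereibacter* (formerly *Rhodobacter*) *sphaeroides*, a purple photosynthetic bacterium, was compared between a strain with the plasmid pRPcrZ and a strain with pR4352, which served as the control, on 2 two-colour Agilent microarrays. Per the labels, both strains grew at low oxygen (0.5 mg/L), RNA of the PcrZ strain carried Cy3 and RNA of the control strain Cy5 on both arrays. Each array held a pool of 3 biological samples per strain, samples 1 to 3 on array 1 and samples 4 to 6 on array 2. The arrays are therefore the replicates (n = 2), and the 6 cultures cannot be separated. No array had the dyes exchanged, and both lay on 1 slide with 1 scan, so a dye effect and the difference between the strains cannot be told apart by the design, and no slide block could be fitted.

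The scanner values were made with Agilent Feature Extraction, per the file headers. The deposited median spot signals and local backgrounds are intensities that were not normalized. The deposited processed signals are intensities that the software had background-subtracted and dye-normalized, and the deposited log ratio is log10 of Cy5 over Cy3 processed signals, per the file headers. The deposited value table of the series holds log2 ratios. For array 2, all 10196 compared probes with 1 spot equalled the log2 of Cy3 over Cy5 background-subtracted signal within 1e-06, so its direction is Cy3 over Cy5. It was not centred, with medians of 0.15 for array 1 and -0.42 for array 2. Its direction for array 1 was checked only by correlation with the ratio of that array's processed signals (r = 0.893, against 0.901 for array 2). This used probes with 1 spot well above background in both channels. A correlation does not depend on scale, so the scale for array 1 was not checked. limma is named in the submitters' processing notes without its version or role.

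The deposited file of array 1 had passed through a spreadsheet that dropped decimal points and kept 3 significant digits. Its processed signals were recovered by dividing by 1000000 and its log ratios by 1000000000. Among spots well above background in both channels, the recovered signals gave a log10 ratio that differed from the recovered log ratio by a median of 3.89e-04. The divisor of the signals cancels in a ratio, so this does not check their scale. Median recovered signals on array 1 were 428 (Cy3) and 419 (Cy5), against 359 and 351 on array 2.

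Before the data were examined, mean spot signals with normexp were to be the main values, with the processed signals of both arrays to take their place if those columns were missing. The files used here do not hold mean spot signals, so the processed signals were used. They were normalized within each array by loess (span 0.3, the 536 control spots at weight 0) in limma 3.58.1 under R 4.3.3, and the log ratio was turned to PcrZ strain (Cy3) over control strain (Cy5). Of 15208 probe spots per array, 1 spot on each array was left out as an outlier, and no spot was saturated. The spots of a probe were averaged, probes well above background in at least 1 channel on both arrays were kept, and the mean was taken over the kept probes of a feature. This left 4081 of 4516 features. Each was tested against a log2 ratio of 0 with limma (lmFit and eBayes, 1 residual degree of freedom, 2.85 prior degrees of freedom), two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The error given with a mean log2 ratio is the SD of the 2 arrays or the moderated standard error (SE), as stated. Cy3 was well above background at 64.3% of probe spots on array 1 and 55.6% on array 2, and Cy5 at 70.9% and 74.3%. The number of arrays limits the precision.

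Where 1 channel was not well above background on both arrays, only a bound is given ("at least N-fold"). It sets the mean log2 signal of the bright strain, after loess and Aquantile, against the dim strain's mean of the higher of its own signal and the lowest signal well above background on that array. Such bounds are open to dye bias, as no dyes were exchanged. They are not strict limits, since a signal not well above background can lie above that lowest signal. For the bounds printed here, other background corrections gave smaller changes.

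The array carries 4372 genes under numeric identifiers and 144 other features with descriptive names. The 19 gene lists fixed before the data were examined (photosynthesis, respiration, stress and others) and the fixed gene symbols could not be looked up. None of the 4372 identifiers, and none of the 33 locus tags within feature names, matched the reference table used here (assembly ASM332471v1), and the files do not pair them with symbols. At most 2 identifiers in each direction are therefore printed. The rule for named genes was the 10 highest and 10 lowest features past the threshold with 1 sign on both arrays, members of the fixed lists, probes for PcrZ and fixed symbols. No probe name holds PcrZ. In place of unnamed genes, all descriptively named regions past the threshold were reported, a choice made after the data were seen. Classes of such regions, and a block of 54 bright identifiers close in number (set apart from other identifiers by gaps of over 20), were tested as sets with camera (preset inter-gene correlation 0.01, Benjamini-Hochberg over 5 sets), with an estimated correlation and fry beside it. These sets too were chosen after the data were seen. Coordinates of intergenic regions are those within the feature names. Their chromosome and genome build are not given in the sources used here, and they were not placed on any genome. Splits of the samples could not be drawn, as there is 1 group of 2 ratios.

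The steps were tested on simulated spots for the comparison of the strains. In these, 200 of 4081 features were changed singly and a set of 54 others was shifted by -0.35 on the log2 scale. The error of each feature was drawn from the prior variance fitted to the real arrays. Of 67 features changed by 0.5 on the log2 scale 19.4% were called, of 67 changed by 1 95.5%, and of 66 changed by 2 98.5%, none with the wrong sign. The set was called lower by camera. Among 3827 unchanged features 9 were called. The simulation holds no dye effects. It gives all probes of a feature 1 shared error, unrelated to brightness and to other features, so its rates may not carry over to the real arrays. Alternatives set before the data were examined were median spot signals without background correction, median centring in place of loess (which coincides here with centred processed signals), no filter or a stricter filter on dim probes, the value table, the median over probes, a trended or robust variance, scale normalization between arrays, single probes, and each array alone. Median signals with normexp (offset 50), features with at least 2 measured probes, features without bounds, and rounding of array 2 were added after the data were seen.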

Results

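The 2 arrays compared RNA of a *C. sphaeroides* strain carrying a plasmid for PcrZ, a small regulatory RNA known to act on photosynthesis genes, with RNA of a control strain at 0.5 mg/L oxygen. The comparison asks which transcripts differ in abundance when PcrZ is expressed from the plasmid. Each array paired pools of 3 biological samples per strain. Median spot signals were 1866 (Cy3, PcrZ strain) and 1299 (Cy5, control strain) on array 1, and 1723 and 1645 on array 2, over local backgrounds of 64 to 72.5. All ratios below are PcrZ strain over control strain as the labels give the dyes. No probe is named for PcrZ, so no probe checked that direction. If the channel labels were exchanged, each higher value and count below would be lower and each lower one higher.

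By the labelled dyes, the lowest ratio of all features was that of the intergenic region IGR_2249 (sense strand, 2381860 to 2382163), which was 17.1-fold lower in the PcrZ strain (17.1-fold higher with the channels exchanged). Its log2 ratio was -3.90 on array 1 and -4.29 on array 2 (mean -4.10, SE 0.13, n = 2, limma adjusted p = 0.0329). The region was measured by 1 probe, bright in both channels, with processed Cy5 signals of 176000 and 112718 against Cy3 signals of 11800 and 5821. The next lowest region, IGR_1263 (sense, 1320298 to 1321302), was 3.72-fold lower (log2 ratio -1.90, SE 0.08, adjusted p = 0.0357). The highest named region was 3'RSP3584, a probe for a gene's 3' end by its name, at 2.54-fold higher (1.35, SE 0.08, adjusted p = 0.0367). Its log2 ratio was 0.67 in the deposited value table.

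Regions outside the numbered genes made up 140 of the 4081 features tested, and 31 of them passed the threshold, 10 higher and 21 lower in the PcrZ strain (limma, adjusted over all features). Adjusted over these regions alone, 16 were higher and 31 lower. Each of the 31 had 1 sign on both arrays, which a call from 2 arrays requires here. Their changes ran from 1.38-fold to 17.1-fold, and 23 were under 2-fold. Of the 31 regions, 18 rested on 1 measured probe. Of the 13 with several probes 12 had all probes in 1 direction, the exception being IGR_0036, a count that the call itself favours. Without the filter on dim probes 27 of the 31 no longer passed, those left being IGR_2249, IGR_1263, IGR_2378 and 3'RSP3584. A region with all its probes already measured kept its log2 ratio there, so for it only the test changed.

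**Figure D1:**
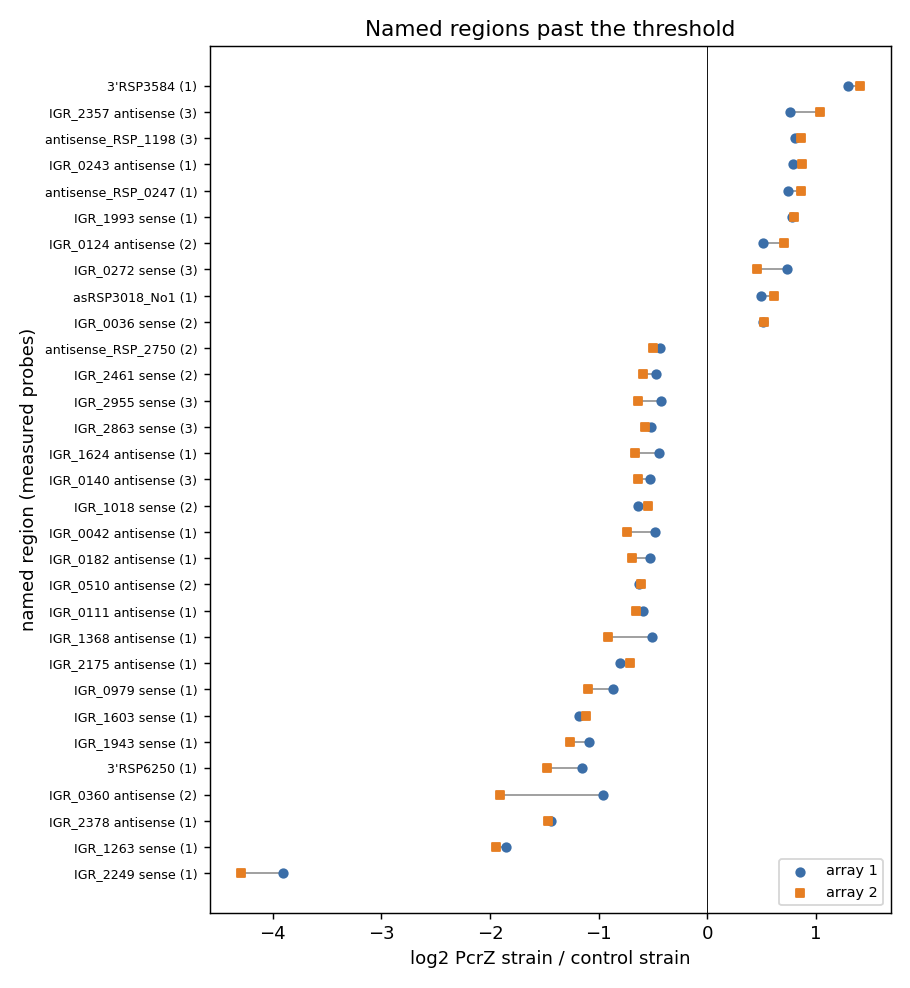
The 31 named regions past the threshold, with the log2 ratio of the PcrZ strain over the control strain on array 1 (circles) and array 2 (squares) and the number of measured probes in brackets. IGR_2249 sense lies at -3.90 and -4.29, and the 10 higher regions lie between 0.46 and 1.40 on each array.

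Among intergenic regions on the sense strand, 9 of 59 fell and 3 rose. After IGR_2249 and IGR_1263, the larger decreases were those of IGR_1943 (2064697 to 2065079), IGR_1603 (1700623 to 1704124) and IGR_0979 (1014869 to 1015270). IGR_1603 and IGR_0979 were 2.21-fold and 1.98-fold lower, and the log2 ratio of IGR_1603 moved from -1.15 to -0.55 with uncorrected median signals and also without the filter. IGR_1943 was not well above background in the PcrZ strain and was at least 2.23-fold lower, while its antisense probe had a log2 ratio of 0.27 and did not pass. Its own log2 ratio of -1.18 shrank to -0.17 with uncorrected median signals, where it did not pass (adjusted p = 0.0591), and to -0.39 with normexp. The remaining decreases were IGR_1018, IGR_2863, IGR_2955 and IGR_2461, with log2 ratios of -0.59, -0.54, -0.54 and -0.53, each from 2 or 3 probes. In the value table IGR_2461 had -1.15, while IGR_1018 (limma adjusted p = 0.0634) and IGR_2863 did not pass. The regions that rose were IGR_1993 (0.78), IGR_0272 (0.59) and IGR_0036 (0.52). IGR_1993 had 0.22 without the filter and 0.34 in the value table and passed in neither (adjusted p = 0.359 and 0.106), and IGR_0272 did not pass with the median over probes (adjusted p = 0.0590). IGR_0036 had 0.10 with uncorrected median signals and did not pass (adjusted p = 0.127). As a class, the sense regions had a mean log2 ratio of -0.21 against -0.03 for other features, which did not pass (camera adjusted p = 0.257, and adjusted p = 0.932 with an estimated correlation). With median signals, other filters on dim probes or the deposited value table the class passed, at adjusted p from 4.14e-05 to 0.0436.

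On the antisense strand of intergenic regions, 10 of 48 fell and 3 rose. IGR_2378 (2509141 to 2509377) was 2.74-fold lower (log2 ratio -1.46, SE 0.08, 1 probe), and IGR_0360 was 2.71-fold lower with log2 ratios of -0.96 and -1.91 on the arrays (SE 0.26, adjusted p = 0.0489). IGR_2175, IGR_1368, IGR_0111, IGR_0510, IGR_0182, IGR_0042, IGR_0140 and IGR_1624 fell by 1.47-fold to 1.69-fold. With uncorrected median signals IGR_0360 had a log2 ratio of -0.49, IGR_2175 one of -0.39 against -0.76, IGR_0182 one of -0.29 against -0.61 and IGR_0111 one of -0.40 against -0.62. In the value table IGR_0360, IGR_0182 and IGR_0111 did not pass (adjusted p = 0.0561, 0.0569 and 0.0513), while IGR_0510, IGR_1368 and IGR_0140 had -1.90, -1.52 and -0.93 there against -0.62, -0.71 and -0.58. IGR_2357 (2491491 to 2491898) rose 1.86-fold on 3 probes, IGR_0243 (255166 to 255569) 1.78-fold on 1 probe and IGR_0124 (140184 to 140533) 1.53-fold on 2 probes. IGR_0124 had 0.37 against 0.61 with uncorrected median signals. IGR_2357 did not pass in the value table (log2 ratio 0.47 against 0.90, adjusted p = 0.109). IGR_0243 had a log2 ratio of -0.30 in the deposited value table (adjusted p = 0.153) and IGR_0036 one of -0.15 when both channels had to be well above background (adjusted p = 0.229), so their direction depended on the values used. The class had a mean log2 ratio of -0.11 and did not pass (camera adjusted p = 0.612).

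Of 20 antisense transcripts to genes, antisense_RSP_1198 rose 1.78-fold on 3 probes, antisense_RSP_0247 rose 1.74-fold on 1 probe, asRSP3018_No1 rose 1.47-fold on 1 probe, and antisense_RSP_2750 fell 1.38-fold on 2 probes. In the value table antisense_RSP_1198 had a log2 ratio of 0.24 against 0.83 and did not pass (adjusted p = 0.191), nor did antisense_RSP_2750 (adjusted p = 0.0664). With uncorrected median signals antisense_RSP_0247 had 0.24 against 0.80 and asRSP3018_No1 0.31 against 0.55. Among 11 gene-end features, 3'RSP6250 fell 2.49-fold and 3'RSP3584 rose, each on 1 probe. The log2 ratio of 3'RSP6250 was -0.63 with uncorrected median signals against -1.32. Neither class passed as a set (camera adjusted p = 0.705 and 0.956), which does not exclude a shift in sets this small. The small RNA probe RSsh2 had a log2 ratio of 0.73 (0.51 and 0.95 on the arrays, adjusted p = 0.0525), just short of the threshold, and RSsh1 one of -0.08 (adjusted p = 0.579). RSsh2 passed under several other settings, such as median signals without and with normexp (adjusted p = 0.00567 and 0.00196) and both channels well above background (0.0174), and did not without the filter (0.0894), in the value table (0.0857), with the robust variance (0.0552) or with array 2 rounded (0.0561).

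Over all features, 192 were higher and 288 lower in the PcrZ strain (limma adjusted p under 0.05), of which 449 were numbered genes, 182 higher and 267 lower. At least 2-fold changes on both arrays were found for 21 features upward and 22 downward. The smallest adjusted p of any feature was 0.0329. With median centring in place of loess the split was 234 higher and 537 lower, 120 and 279 with the value table, and 8 and 4 without the filter on dim probes. The excess of lower calls was absent among features with at least 2 measured probes, of which 141 were higher and 141 lower. Features with only a bound held 2 of the higher and 65 of the lower calls. Among features measured in both channels on both arrays, 173 were higher and 191 lower. Features with 1 measured probe made up 198 of the 480 calls, and 147 of these were lower.

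**Figure D2:**
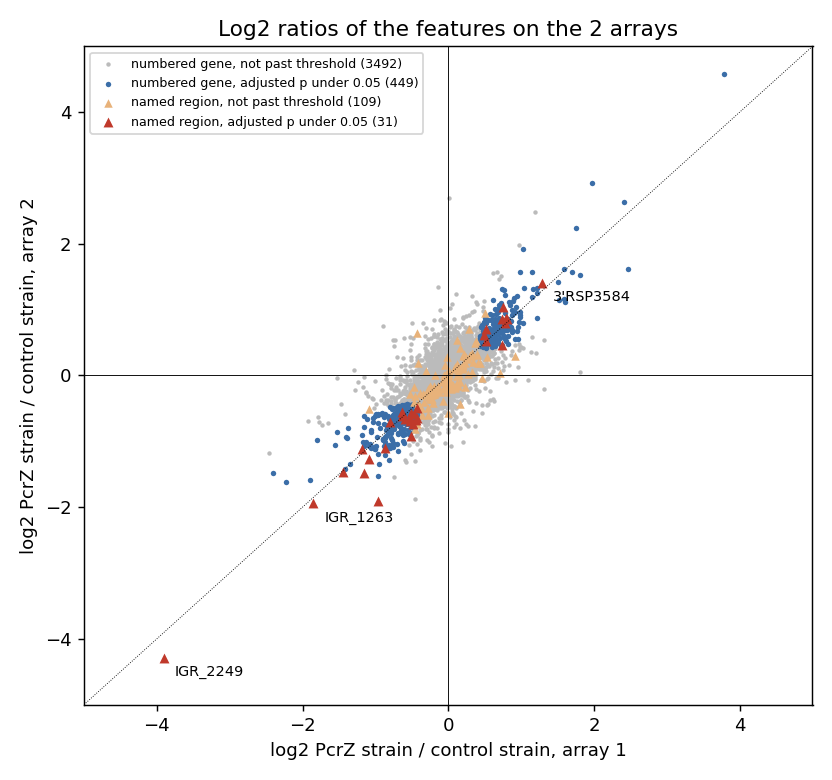
Log2 ratio of the PcrZ strain over the control strain on array 1 (x axis) and array 2 (y axis) for the 4081 features tested, with numbered genes as circles, named regions as triangles and those past the threshold in darker colours. IGR_2249 lies apart at -3.90 and -4.29, and the ratios correlate with r = 0.742 across features.

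The files do not pair the numbered genes with symbols. The gene with the highest fitted ratio, identifier 640071052, was at least 8.03-fold higher in the PcrZ strain by the processed signals (limma adjusted p = 0.0357). The control strain was not well above background, and 1 of 3 probes was measured. Identifier 640069563 was 5.75-fold higher on 3 probes that all pointed 1 way (log2 ratio 2.52, 2.41 and 2.64 on the arrays, SE 0.10, adjusted p = 0.0357). The gene before it in number and the next genes after it had log2 ratios of 1.63, 1.46 and 1.67, each on 3 probes and past the threshold, while the genes on either side of this run had 0.01 and 0.03 and did not pass. The gene next below in number was higher again (0.81 on 3 probes, adjusted p = 0.0367). The genes with the lowest fitted ratios, 640070229 and 640071892, were at least 2.39-fold and at least 2.10-fold lower on 1 probe each (adjusted p = 0.0380 and 0.0367). The PcrZ strain was not well above background for either, so their place among the lower genes is not settled, and a gene not printed here was 2.68-fold lower on 3 probes with both channels measured. The sizes of all 4 depended on the background correction. With uncorrected median signals the log2 ratios were 0.92 for 640071052 and 0.70 for 640069563, and -0.30 for 640070229 and -0.36 for 640071892. With normexp they were 2.03, 1.37, -0.67 and -0.86 in the same order, so the bounds are those of the processed signals. With both channels well above background 640069563 had 1.90. Without the filter on dim probes 640071052, 640070229 and 640071892 had 1.19, -0.78 and -0.73 and did not pass (adjusted p = 0.0598, 0.0812 and 0.0695), nor did 640069563 and 640071892 with the value table (0.0738 and 0.465). A block of 54 bright identifiers close in number, chosen after the values were seen, had a median log2 ratio of -0.36, with 16 genes lower, 0 higher and 44 below 0 on both arrays (camera adjusted p = 3.21e-07, adjusted p = 0.637 with an estimated correlation). Adjusted over the block alone, 4 were higher and 35 lower.

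Across features, which are not independent replicates, the ratios of the arrays had Pearson r = 0.742 and Spearman rho = 0.705, and 76.2% of features had 1 sign on both. Probes of one gene were less alike between arrays than 1 probe was with itself. The same probe correlated between arrays with r = 0.698. A probe on array 1 and a different probe of the same gene on array 2 correlated with r = 0.229. Of 282 features past the threshold with at least 2 measured probes, 261 had all probes in 1 direction, a count that the call itself favours.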

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

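The spots named E1A, control spots outside the comparison of the strains, gave signal where the negative control spots did not. On array 1, 40 of 200 E1A spots were well above background in Cy3 and 63 in Cy5. On array 2, 6 were in Cy3 and 92 in Cy5. On both arrays 0 of 77 negative control spots were, in either channel. What was added to the samples for these spots is not given in the sources used here.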

How the results depend on the processing

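Normexp, the limit to 2 probes, the removal of bounds, the rounding of array 2 and the tests of classes were chosen after the data were seen. The number of calls depended on the setting: against 192 features higher and 288 lower, median signals without background correction gave 603 and 728, normexp 698 and 891, both channels well above background 499 and 513, a variance trend 388 and 480, single probes 454 and 548, and no filter 8 and 4 (1260 at an unadjusted p under 0.05). Median centring gave 537 lower, at least 2 probes gave 164 higher and 158 lower, without the excess of lower calls, and 120 were higher with the value table. The cause was not tested, except that single probes and at least 2 probes change what is tested. Of the features called, 1 was called in the opposite direction with both channels well above background, and 0 under the other settings. The count of features at least 2-fold changed on both arrays (21 higher, 22 lower) was 3 and 7 with uncorrected median signals, 13 and 8 with normexp and 11 and 4 with at least 2 probes. The lower count was 39 with median centring, 6 without a filter, 12 with both channels, 87 with the value table and 13 without bounds. On a single array, 32 to 52 were higher, and 57 were lower on either. The correlation of the arrays was 0.827 and 0.827 with median signals, without and with normexp, 0.629 without a filter, 0.800 with both channels, 0.702 with the value table and 0.716 with at least 2 probes. Leaving out an array otherwise leaves values with no test.

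IGR_2249, IGR_1263, IGR_2378 and 3'RSP3584 kept their call under each of the 12 settings in which they were followed. Each rested on 1 probe, so the limit to 2 probes left them out, and they were not followed with single probes. For 3'RSP3584 the limma adjusted p was 0.0499 without a filter and 0.0483 in the value table. Of the 31 regions, 27 lost theirs without a filter, 11 with the value table, 5 with array 2 rounded, 5 with the robust variance, 2 with uncorrected median signals and 1 with the median over probes, as did IGR_0036 with both channels. IGR_0036 turned to -0.15 with both channels well above background and IGR_0243 to -0.30 in the value table. For sets, given as the mean log2 ratio less that of other features, intergenic sense regions passed at -0.20 with uncorrected median signals, -0.23 without a filter, -0.22 with both channels, -0.43 with the value table and -0.22 with normexp, and intergenic antisense regions at -0.31 with the value table. Shifts that did not pass changed sign for antisense transcripts (-0.0061 with the value table) and gene ends (-0.046 without a filter, -0.042 with both channels, -0.027 with the value table, -0.0017 with scale normalization). Gene ends also had 0.061 on array 1 alone and -0.058 on array 2 alone. The block of bright identifiers, at -0.30, did not pass with an estimated correlation at that same value. It did not pass with fry either, which tests the set against no change and not against other features. The block passed under the other settings with a test, at -0.30 to -1.55. The 19 fixed gene lists were not run. Signal over background limits the results, since 232 features had only a bound and 67 of these were among the calls, 65 of them lower.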

Other observations

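The tests of single-probe effects, brightness, spot defects, dye effects on the block and exchanged labels were chosen only after the result was seen. Numbered genes that followed each other in number had similar log2 ratios, with r = 0.204 over 3562 pairs, against at most 0.070 in 10000 shuffles (permutation p = 1e-04, one-sided, the smallest these can give). The files do not state whether such genes lie side by side.

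The arrays resembled each other more for one probe than for different probes of one gene (r = 0.698 and 0.229). Position on the slide accounts for little of it. Over 1315 probes with 2 spots, 1 spot correlated with itself between arrays at r = 0.673 and 2 spots at different positions at 0.634. The latter exceeded different probes of one gene by 0.405, a comparison of unlike sets of probes. Dim spots do not account for the difference either. Among probes well above background in both channels of both arrays, the same probe exceeded different probes of one gene by 0.412. Effects that differ from probe to probe are not the whole of the agreement. Different probes of one gene correlated between arrays at 0.229 (95% interval 0.196 to 0.262). Dye effects that the probes of a gene share could also give this, and were not tested. Effects of single probes may still hold the larger part, as may unequal change along a transcript or a difference between the strains. Adjusted p values from these arrays can therefore count a dye effect of a probe as a change.

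IGR_2249, 17.1-fold lower on 1 probe, was weighed against 4 technical explanations. A trend with brightness that other features share does not account for it. The 100 features nearest in Cy5 brightness had log2 ratios from -0.96 to 1.27, with a median of -0.22. That 0 of them lay at or below -2 decides nothing further, since the region was picked as the lowest of all. The next lowest feature past the threshold had -1.94, so no other such feature of any brightness reached -2. A defect of 1 spot does not account for the ratio either, since the arrays differed by 0.39. A dye effect of this probe stays open: 0% of 6756 probes of genes with 3 measured probes differed from the others of their gene by 4 or more, but the region was picked as the extreme and no dyes were exchanged, so its rarity does not exclude it. Exchanged channel labels also stay open, because 0 probes are named for PcrZ. One intergenic region far brighter in 1 channel is what an overexpressed small RNA might look like in the channel of its strain, and whether this region holds PcrZ was not settled here, so the direction of all ratios rests on the labels and would turn if they were exchanged, and a true decrease in the PcrZ strain remains possible.

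The block of 54 bright identifiers close in number was lower, with a median log2 ratio of -0.36. Its brightness stays open as a cause: the difference from the median of 13 other features as bright was -0.25 (95% bootstrap interval -0.53 to -0.0048), but the interval barely excludes 0, and 11 of the 13 are named regions, so only 2 genes were as bright. The loess curve applied here is not the cause, since the median was -0.42 with median centring in its place. The size depended on the values used: the block's mean less that of other features was -1.55 in the value table, against -0.30 as reported. For array 2 the value table has no dye normalization, and for array 1 this was not checked. A dye effect on RNAs of this kind cannot be told apart from a difference between the strains, as 0 arrays had the PcrZ strain in Cy5, and the set did not pass with an estimated correlation.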
